A study of Mus musculus and Homo sapiens with 8 samples.

How the data were processed

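m6A-CLIP and PolyA-Seq were run on mouse brain (postnatal day 2), mouse liver (adult), human CD8 T cells and the A549 lung carcinoma line, giving 8 samples, 1 per assay and tissue or cell type. A549 cells were transfected with siRNAs, given another dose at 48 h and harvested at 96 h, per the labels' protocols. PolyA+ RNA was cut to fragments of 20 to 80 nt, and 3 ug of it was incubated with 25 ug of antibody against m6A, per the labels' protocols. The 4 m6A-CLIP samples entered the analysis. The PolyA-Seq samples were not analysed here.

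Each m6A-CLIP sample had a deposited list of peak regions and a deposited list of precise m6A sites in BED format. The authors' score column held the value 2 for every peak region and 1 for every site, so the score ranked nothing and was not used. Coordinates are in mm9 for mouse and hg18 for human, as the deposited lists are labelled. The submitters' processing notes name Novoalign, Bowtie2, TopHat2 and bedtools and the builds mm9, hg18 and hg19, without saying which step used which. The peak caller, the site caller and their thresholds are not given in the sources used here. The authors' list of replicates names 3 for brain, 4 for liver, 3 for CD8 T cells, and 3 wild-type and 3 knockdown for A549. Each sample has 1 merged list, so how the replicates were combined could change which regions and sites appear, and no spread between replicates could be computed.

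Several traits of the lists were checked because they bear on the measurements. All sites lay inside the region their name gives, on the same strand. Between 98.9% (brain) and 99.9% (liver) of region starts, in genome coordinates, lay on a 10 nt grid. Region ends were not checked. Regions of 400 nt or more were split into parts, which gave 1347 entries in brain, 70 in liver, 778 in CD8 T cells and 1253 in A549. Of the numbers in region names, 9.69% were unused in brain, 12.2% in liver, 9.21% in CD8 T cells and 10.4% in A549, and why is not stated in the sources used here. The brain lists alone had entries on unplaced sequences, 49 regions and 36 sites. Each site name holds a trinucleotide and an ordinal. Later sites of a region always had higher ordinals, with at least 3 nt per step, and in regions of both libraries of a species 369 pairs of shared sites in mouse and 1100 in human had equal ordinal steps in both. No source used here says what the ordinal counts. It was read as counting RAC trinucleotides from the 5' end of the region, and every value that uses RAC candidates rests on that reading, which gave 32.7 candidates per kb up to the last site in brain, 34.7 in liver, 32.6 in CD8 T cells and 32.1 in A549. The density leaves the last site itself out. For the share listed, candidates up to and including the last site were counted, in regions with a site only. Of these 44.7% were listed in brain, 48.4% in liver, 45.2% in CD8 T cells and 44.8% in A549. The last site is listed by definition, which raises these shares, and they do not hold for whole regions.

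The planned comparisons, the chance values from random positions, the rule for named regions and most alternatives were fixed before the data were examined. Sites of 2 libraries matched when they lay within 2 nt on the same strand, and regions matched when they overlapped by 1 nt or more. Spacing was compared with 100 seeded random placements within each library's own regions. Chance sharing came from 100 placements at random positions where regions of both libraries overlap. The chance value from random RAC trinucleotides, the count over candidates, the multiples of 3 nt, the position within regions, the GAC comparisons, and the counts by chromosome and by what the other library lists in a window were added after the data were seen. Shares carry exact Clopper-Pearson 95% intervals. Bootstrap intervals come from 1000 draws of blocks of 1000000 nt, since neighbouring sites are not independent, and they too leave out the spread between replicates. No p-value is given, because each group has 1 list.

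Named regions follow a fixed rule. With gene names, it would have taken the genes with most sites, those with sites in one library and none in the other, those with most shared sites, and members of gene lists fixed beforehand. The files pair no site with a gene and no genome or annotation of mm9 or hg18 was used here, so the rule was applied to same-strand windows of 1000 nt counted from the chromosome start, up to 5 per library and direction. For the same reason the gene lists, the mouse to human overlap, the share of sites in last exons, distances from the last exon or stop codon, and the longer m6A motifs were not run. This departs from the planned gene-level results. A mouse gene table of another build (GRCm38) was not used, since coordinates were not converted between builds. Named windows leave out the sex chromosomes and unplaced sequences, and no X or Y counts are given for human samples.

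Alternatives covered strand, regions extended by 10 nt, unplaced sequences left out, neighbour limits of 50 and 200 nt, match limits of 0, 10 and 50 nt, an overlap of 50% of both regions, longer lists thinned to the shorter, windows with 2 or more sites, windows from region middles, windows moved by 500 nt, and subsets of sites by number per region. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. The statistics were tested on simulated data with known answers before use. For brain and liver, a true GAC difference of 8 points over 8748 simulated sites was recovered as 8.89 (6.74 to 10.9). A share of 40% at multiples of 3 came out as 40.9% (39.2 to 42.6%) and an offset of -5 nt as -5.05 nt. For CD8 T cells and A549, with 23479 simulated sites for the GAC difference, the same quantities were 8.42 (7.10 to 9.74), 40.2% (38.6 to 42.0%) and -4.95 nt. The gaps and offsets were drawn directly, so reading them from lists was not tested. The share of sites shared was recovered without error in both pairs. Simulated sites not copied were placed away from every site of the other list, so only the counting was checked.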

Results

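N6-methyladenosine (m6A), a methylated adenosine within messenger RNA, was mapped in mouse brain and liver and in human CD8 T cells and A549, a lung carcinoma cell line. In m6A-CLIP, RNA fragments bound by an antibody against m6A are crosslinked to it, so that the modified base can be placed at a single position. The series holds 8 samples, 4 of m6A-CLIP and 4 of PolyA-Seq, 1 of each per tissue or cell type; the PolyA-Seq samples were not analysed here. Each m6A-CLIP sample came as a list of peak regions and a list of single-nucleotide sites, in mm9 coordinates for mouse and hg18 coordinates for human. The authors' list of replicates names 3 for brain, 4 for liver, 3 for CD8 T cells, and 3 wild-type and 3 knockdown for A549, but the lists give no values per replicate. Read depth behind a region or site is therefore unknown, and no difference between tissues could be set against a spread between replicates. Intervals are 95% intervals, exact Clopper-Pearson unless a bootstrap is named, and cover counting error only. Whether sites lie in last exons, the subject of the series title, was not analysed here, because no annotation of these builds was used.

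Brain had the longest lists, with 38164 peak regions and 30078 sites, and liver the shortest, with 13137 regions and 8748 sites. CD8 T cells had 27495 regions and 19682 sites, and A549 had 36702 regions and 23479 sites. The density of sites differed less than their number. It was 6.54 sites per kb of peak region in brain, 6.93 in liver, 6.26 in CD8 T cells and 5.46 in A549. The regions covered 4602 kb in brain, 1263 kb in liver, 3144 kb in CD8 T cells and 4299 kb in A549. Their median width was 80 nt in liver and 100 nt in the other lists, within a range of 40 to 390 nt. The number of listed sites follows the authors' thresholds as well as the tissue, and those thresholds are not given in the sources used here.

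Most peak regions held either no precise site or a single one. In brain 48.8% of regions held a site (48.3 to 49.3%), in liver 45.4% (44.5 to 46.2%), in CD8 T cells 46.0% (45.4 to 46.5%) and in A549 39.5% (39.0 to 39.99%). A549 regions were the least often resolved to a base. Regions with 2 or more sites made up 18.4% in brain, 13.8% in liver, 15.8% in CD8 T cells and 13.9% in A549, yet held 61.4%, 52.6%, 57.8% and 59.9% of the sites. The most sites in 1 region were 10 in brain, 13 in liver, 15 in CD8 T cells and 11 in A549. Sites placed at random within the same regions left fewer regions empty in A549, 55.8% on average over 100 draws against 60.5% observed, and in brain, 49.4% against 51.2%. In CD8 T cells 52.3% were left empty at random against 54.0% observed. In liver the observed 54.6% exceeded every draw as well (52.9 to 54.4%). Regions with a site were wider than those without, with medians of 130 against 80 nt in brain, 100 against 70 nt in liver, 120 against 80 nt in CD8 T cells and 130 against 80 nt in A549.

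Sites lay close together in all 4 lists. A neighbouring site within 100 nt on the same strand was found for 57.7% of brain sites, 50.9% of liver sites, 54.4% of CD8 T cell sites and 56.6% of A549 sites. Random placement within the same regions gave 55.6%, 51.4%, 52.6% and 49.0%. A549 sites were thus 1.16 times as often close to another site as at random, brain sites 1.04 times and CD8 T cell sites 1.03 times. With the number of sites in each region kept and only their positions drawn at random, a comparison chosen after the data were seen, A549 stood at 1.03 times (range over the draws 1.02 to 1.04), brain and CD8 T cells at 1.02 times each, and liver at 1.01 times (0.998 to 1.02). With random placement over all regions, liver sites lay inside the range of the draws (49.9 to 52.8%). With a limit of 50 nt the ratio to random was 1.09 in liver, the lowest, 1.14 in brain, 1.14 in CD8 T cells and 1.35 in A549. All these placements were even over a region, whereas listed sites gathered near its middle. Such gathering can bring sites closer, so a ratio above 1 does not by itself show that sites cluster with each other. Within a region the median gap between neighbouring sites was 30 nt in brain, 24 nt in liver, 28 nt in CD8 T cells and 26 nt in A549, and the smallest was 3 nt. Gaps of 4 to 60 nt were a multiple of 3 nt for 37.6% of neighbours in brain (bootstrap interval 36.5 to 38.6%), 37.0% in liver (35.1 to 39.1%), 36.6% in CD8 T cells (35.2 to 37.9%) and 36.0% in A549 (34.9 to 37.1%). An even spread would give 33.3%, which lies below all 4 intervals.

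**Figure D1:**
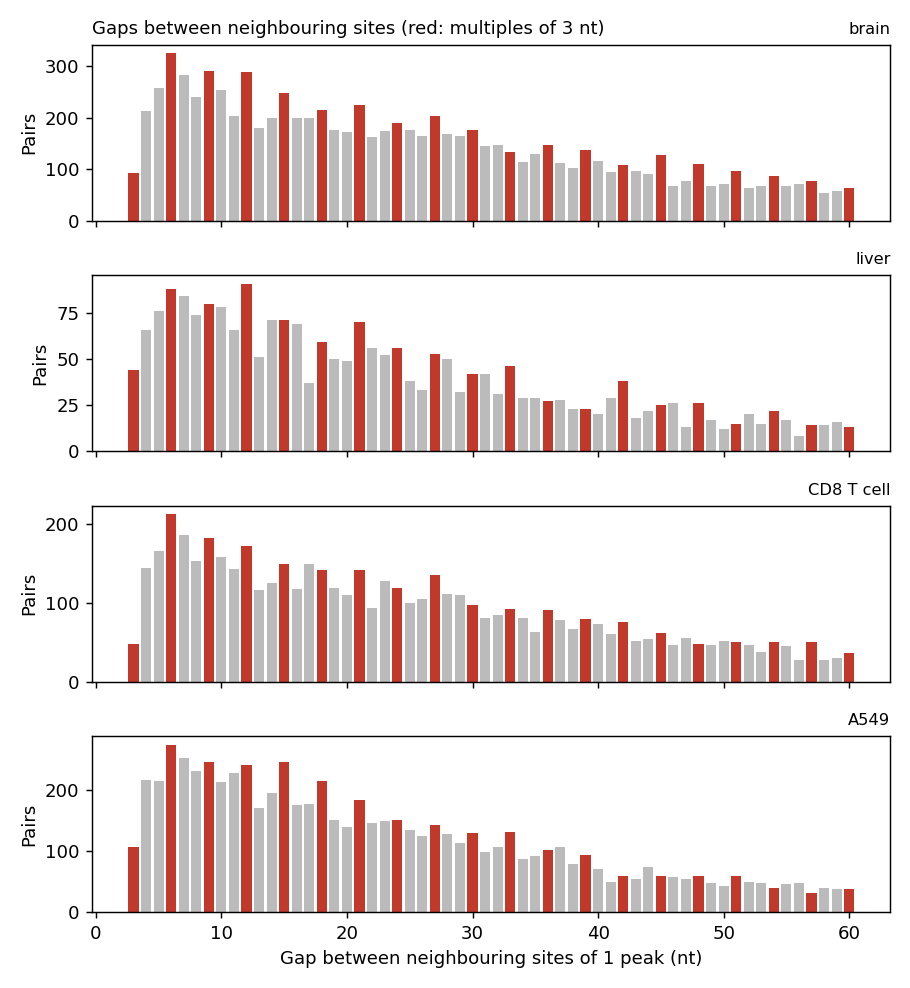
Number of neighbouring site pairs within 1 peak region (vertical axis) at each gap in nt (horizontal axis), one panel per library, with multiples of 3 nt in red. Multiples of 3 nt hold 37.6% of the gaps of 4 to 60 nt in brain, 37.0% in liver, 36.6% in CD8 T cells and 36.0% in A549.

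The deposited names place each site at the A of a GAC or an AAC trinucleotide, both forms of the RAC core (R, a purine) of the m6A motif. GAC was the more frequent in every library. It made up 68.1% of sites in brain (67.6 to 68.7%), 66.1% in A549 (65.5 to 66.7%), 65.5% in liver (64.5 to 66.5%) and 64.3% in CD8 T cells (63.6 to 65.0%). Regions with a single site had the highest GAC shares, 72.0% in brain, 67.9% in liver, 68.3% in CD8 T cells and 68.8% in A549. In regions with 3 or more sites the shares were 64.7%, 61.6%, 59.99% and 62.9%, and in each library their interval lay below that of single-site regions. The GAC share of all RAC trinucleotides in these regions was not analysed here, so the values describe the listed sites and not a preference.

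**Figure D2:**
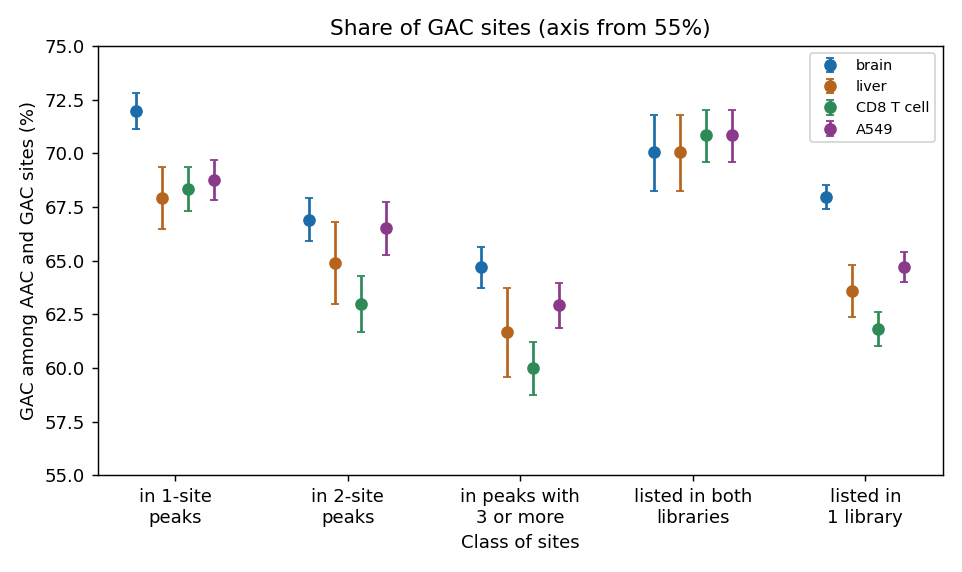
Share of GAC among the listed sites (vertical axis, percent, starting at 55%) by number of sites in the region and by whether the position was listed in both libraries of a species. Points are libraries and bars are exact 95% intervals; brain falls from 72.0% in single-site regions to 64.7% in regions with 3 or more sites, and CD8 T cells from 68.3% to 59.99%.

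Within their regions, sites of all 4 libraries lay towards the 5' end of the RNA. The mean distance from the middle was -8.18 nt in brain (bootstrap interval -8.71 to -7.69 nt), -8.07 nt in liver (-8.82 to -7.32 nt), -9.07 nt in CD8 T cells (-9.69 to -8.44 nt) and -7.65 nt in A549 (-8.30 to -7.01 nt), where negative values are 5' of the middle. The shift differed by strand. In genome coordinates, where 5' is negative on the plus strand and positive on the minus strand, the means were -4.30 nt (plus) and 12.1 nt (minus) in brain, -4.03 and 12.5 nt in liver, -5.19 and 13.3 nt in CD8 T cells, and -3.69 and 11.8 nt in A549. On the 5' side of the middle lay 59.7% of brain sites, 63.4% of liver sites, 61.4% of CD8 T cell sites and 59.7% of A549 sites.

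**Figure D3:**
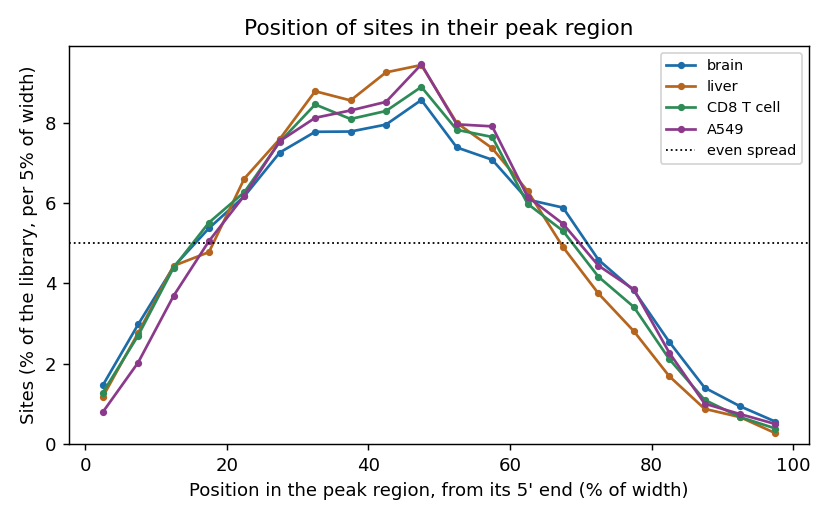
Distribution of sites along their peak region, with the position from the 5' end in percent of the width on the horizontal axis and the share of each library's sites per 5% of width on the vertical axis. Lines are the 4 libraries and the dotted line is an even spread; the median position is 43.7% of the width in brain, 42.3% in liver, 42.9% in CD8 T cells and 44.3% in A549.

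The brain and liver lists tell how far m6A positions coincide between mouse tissues, with postnatal day 2 brain set against adult liver. Exactly 2630 positions were listed in both, 30.1% of liver sites (29.1 to 31.0%) and 8.74% of brain sites (8.43 to 9.07%). Most liver sites, 75.4%, lay in a brain peak region, whereas 29.5% of brain sites lay in a liver region. Of liver regions 68.2% overlapped a brain region (67.4 to 69.0%), and of brain regions 22.7% overlapped a liver region (22.3 to 23.1%). Both site shares count the same 2630 positions and differ only by the length of the lists. Thinning the brain list at random to the length of the liver list therefore gives, by construction, a liver share close to that of brain, 8.72% of sites, and left 23.97% of liver regions shared. Among sites in regions of both tissues, 29.6% of brain and 39.9% of liver sites were shared. Regions found in both tissues more often held a site than the others, 67.9% against 43.2% in brain and 51.1% against 33.2% in liver, but they were also wider, with medians of 130 against 90 nt in brain and 90 against 70 nt in liver.

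Several 1 kb windows carried many sites in one mouse tissue and none in the other. The window with most brain sites, on chromosome 1 from 42756001 to 42757000 (plus strand, mm9), held 14 sites in 5 brain regions and no liver region. Windows on chromosome 4 from 68423001 to 68424000 (minus strand) and on chromosome 12 from 50486001 to 50487000 (plus strand) each held 13 brain sites and no liver region. On chromosome 2, from 28085001 to 28086000 (plus strand), 13 brain sites stood against 2 liver regions without a site, and from 97470001 to 97471000 (plus strand) 12 brain sites stood against 1 such region. The window with most liver sites, on chromosome 3 from 82835001 to 82836000 (plus strand), held 17 sites in 3 liver regions and no brain region. Liver sites without a brain region also numbered 14 on chromosome 9 from 46078001 to 46079000 (plus strand), 11 on chromosome 7 from 126754001 to 126755000 (minus strand) and 11 on chromosome 12 from 8015001 to 8016000 (plus strand). On chromosome 10, from 79798001 to 79799000 (plus strand), 10 liver sites stood against 3 brain regions without a site. The most shared positions in a window were 6, on chromosome 2 from 84551001 to 84552000 (minus strand) with 9 brain and 6 liver sites, and on chromosome 9 from 71331001 to 71332000 (minus strand) with 8 brain and 7 liver sites. On chromosome 3, from 121717001 to 121718000 (plus strand), 11 brain and 14 liver sites shared 5 positions. Of all windows with a site, 3161 had one in both tissues, 64.1% of 4935 liver windows and 23.3% of 13572 brain windows; with all lists thinned to the shortest, the liver share was 34.7%. The files pair no window with a gene, so whether a window without sites was transcribed in that tissue is not known here.

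Random positions within regions of both tissues lay within 2 nt of 4.30% of liver sites and 1.26% of brain sites. The observed shares were 6.999 and 6.95 times as large. All observed matches were exact, so these ratios set exact matches against random ones within 2 nt. Since all sites lie at RAC, a stricter chance value came from random RAC trinucleotides at the density read from the site names. That reading takes the number in each name as a count of RAC, which no source used here states. The chance value was 22.0% of liver sites and 7.07% of brain sites, and the observed shares were 1.37 and 1.24 times as large. A count over RAC candidates read likewise from the names took only sites 5' of the other tissue's last site in a region. Of 2806 such liver sites 39.4% were listed in brain, against 29.8% if positions were drawn at random. The excess was 9.63 percentage points (bootstrap interval 8.26 to 11.0). Of 2346 such brain sites 31.3% were listed in liver against 26.2%, an excess of 5.18 points (3.85 to 6.49). The random RAC value and this count both take every RAC of a region as equally likely to be listed. Listed sites gathered near the middle, however. In brain 8.56% lay at 45 to 50% of the width and 0.562% at 95 to 100%. Lists with the same profile would match above these values without agreeing on particular positions, so the excess does not measure such agreement alone. The longer brain list limits the share it can have in common with liver.

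CD8 T cells and A549 give the corresponding comparison of a primary immune cell and an epithelial tumour line, the latter transfected with siRNAs. The lists had 5462 positions in common, 27.8% of CD8 T cell sites (27.1 to 28.4%) and 23.3% of A549 sites (22.7 to 23.8%). In a region of the other library lay 72.5% of CD8 T cell sites and 63.6% of A549 sites. Of CD8 T cell regions 63.2% overlapped an A549 region (62.6 to 63.8%), and of A549 regions 46.9% overlapped a CD8 T cell region (46.4 to 47.4%). Regions found in both held a site more often than the others, 52.6% against 34.6% in CD8 T cells and 51.5% against 28.9% in A549, and were wider, with medians of 110 against 80 nt and 120 against 80 nt. Among sites in regions of both, 38.3% of CD8 T cell and 36.6% of A549 sites were shared.

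The human window with most CD8 T cell sites lay on chromosome 19 from 6615001 to 6616000 (minus strand, hg18) and held 19 sites in 4 regions. A window on chromosome 5 from 35913001 to 35914000 (plus strand) held 18 CD8 T cell sites. Windows on chromosome 6 from 159377001 to 159378000, chromosome 8 from 134119001 to 134120000 and chromosome 17 from 26669001 to 26670000 (all minus strand) held 15 each, and on chromosome 17 only 2 of the 15 were GAC. None of these 5 windows had an A549 region. The window with most A549 sites and none in CD8 T cells lay on chromosome 1 from 94412001 to 94413000 (minus strand), with 18 sites in 3 regions. It was followed by 15 A549 sites on chromosome 6 from 83132001 to 83133000 and on chromosome 15 from 30716001 to 30717000, and by 13 on chromosome 1 from 200251001 to 200252000 and on chromosome 5 from 82871001 to 82872000 (all plus strand). None of these 5 windows had a CD8 T cell region. The most shared positions, 11, lay on chromosome 3 from 37008001 to 37009000 (minus strand), with 16 CD8 T cell and 18 A549 sites. On chromosome 14, from 49158001 to 49159000 (plus strand), 10 CD8 T cell and 15 A549 sites shared 8 positions. Windows on chromosome 1 from 148816001 to 148817000 and chromosome 9 from 134761001 to 134762000 (both minus strand) shared 8 of 9 sites each. In all, 5037 windows had a site in both, 51.8% of 9729 CD8 T cell windows and 45.4% of 11094 A549 windows. Cell type, origin and siRNA transfection differ together between these libraries, and whether the A549 list includes the knockdown replicates is not stated in the sources used here.

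**Figure D4:**
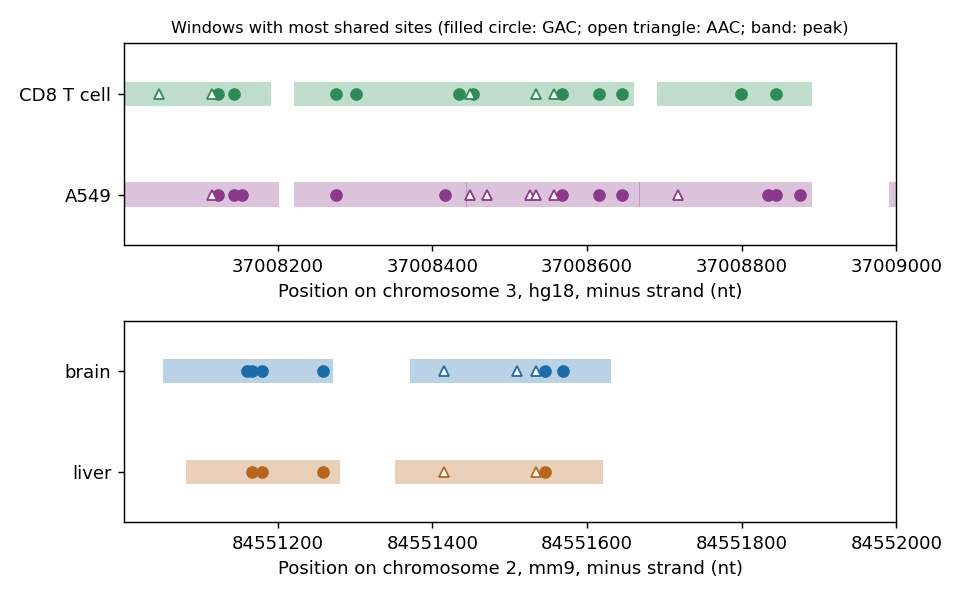
The 1 kb windows with most shared sites, human (upper panel, chromosome 3, hg18) and mouse (lower panel, chromosome 2, mm9), with the genome position in nt on the horizontal axis and a line for each library. Bands are peak regions, filled circles GAC sites and open triangles AAC sites; 11 positions coincide in the human window and 6 in the mouse window.

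Random positions within regions of both cell types lay within 2 nt of 3.27% of CD8 T cell sites and 2.74% of A549 sites. Random RAC trinucleotides would have matched 18.2% of CD8 T cell sites and 16.3% of A549 sites, and the observed shares were 1.53 and 1.43 times as large. The count over candidates read from the names took only sites 5' of the other library's last site in a region. Of 5085 such CD8 T cell sites 45.2% were listed in A549 against 32.3% at random. The excess was 12.9 percentage points (bootstrap interval 11.9 to 13.8). Of 5178 such A549 sites 38.1% were listed in CD8 T cells against 28.5%, an excess of 9.60 points (8.68 to 10.5). As in mouse, every RAC of a region was taken as equally likely to be listed, although sites gathered near the middle. Sharing grew with the distance allowed. Within 50 nt of a site of the other library lay 44.9% of CD8 T cell sites, 41.2% of A549 sites, 54.5% of liver sites and 17.8% of brain sites. Within 1000 nt the shares were 64.1%, 60.3%, 71.5% and 32.7%, and within 10000 nt they were 69.9%, 64.7%, 74.99% and 37.6%. With the other list moved along the chromosome, at most 5.25% of the sites of any library had a site within 10000 nt.

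**Figure D5:**
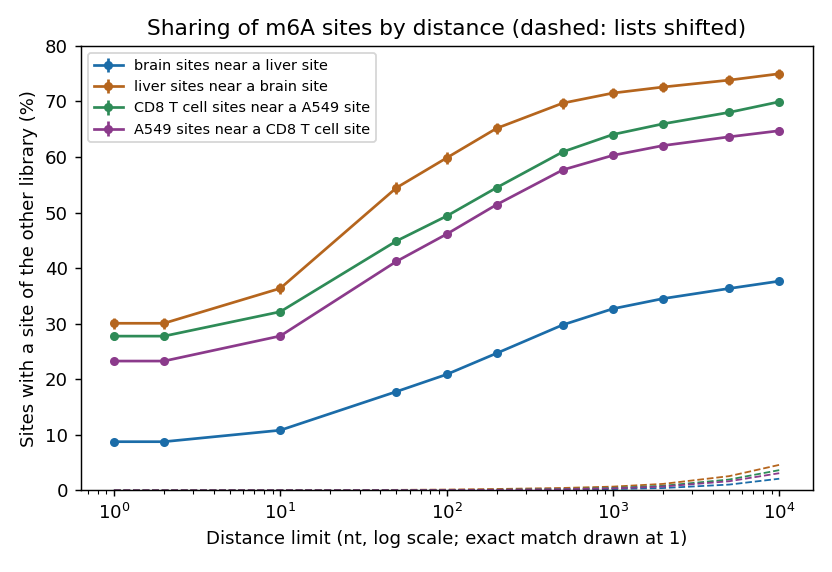
Share of each library's sites (vertical axis, percent) with a same-strand site of the other library of that species within the distance on the horizontal axis (nt, log scale, with exact matches drawn at 1). Bars are exact 95% intervals and dashed lines are the mean for lists moved along the chromosome; liver rises from 30.1% at exact matches to 71.5% within 1000 nt, and brain from 8.74% to 32.7%.

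Positions listed in both libraries of a species were more often GAC. In mouse, 70.04% of the shared positions were GAC, against 63.6% of the liver sites and 68.0% of the brain sites not shared. In human, 70.8% of the shared positions were GAC, against 61.8% of the CD8 T cell sites and 64.7% of the A549 sites not shared. The difference was 9.02 percentage points in CD8 T cells (block bootstrap interval 7.51 to 10.5), 6.44 in liver (4.21 to 8.65), 6.12 in A549 (4.73 to 7.51) and 2.09 in brain (0.173 to 4.13), and all 4 intervals lay above 0. Among sites in regions of both libraries alone, a comparison chosen after the data were seen, the order changed, with 6.58 points in brain (4.44 to 8.76), where 63.5% of the sites not shared were GAC, 4.26 in liver (2.01 to 6.64), 9.48 in CD8 T cells (7.96 to 11.0) and 8.03 in A549 (6.41 to 9.58). In liver, sites outside any brain region had the lowest GAC share, 59.6% (57.5 to 61.7%), while brain sites outside any liver region reached 69.3% (68.6 to 69.9%).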

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

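The alternatives that change the GAC share, the GAC difference, the number of sites kept per region and the window position were chosen after the data were seen; the others were planned. Of 104 alternatives to 32 values, 66 left the value within its interval or on its side of the comparison, 36 moved it and 2 reversed it. Both reversals concern liver spacing, which rose above random to 1.09 times within 50 nt, where the cause was not tested, and to 1.09 times in regions with 2 or more sites, where choosing regions by their observed sites gives a ratio above 1 by construction, so that it is no evidence of clustering. Strand, extended regions, unplaced sequences, exact matching and moved windows left every value they were run on within its interval. Some of the 66 were fixed or nearly fixed by construction and are no evidence of stability. The share of sites in a region was 100%, which ignoring strand, extending regions or leaving out unplaced sequences could not lower. Sites at RAC cannot lie 1 or 2 nt apart, so exact matching had to equal matching within 2 nt. Thinning the longer list at random leaves the share of that list itself unchanged on average. The GAC difference stayed above 0 in all 4 libraries under both of its alternatives.

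The GAC share in single-site regions was 72.0% in brain, 67.9% in liver, 68.3% in CD8 T cells and 68.8% in A549, above that of all sites; the cause was not tested. The other moved values come from looser or stricter matching, a narrower set of sites or windows, regions in place of sites, or shorter lists. For site sharing, in the same order of libraries, a limit of 10 nt gave 10.8, 36.4, 32.1 and 27.8%, a limit of 50 nt gave 17.8, 54.5, 44.9 and 41.2%, and sites in overlapping regions alone gave 29.6, 39.9, 38.3 and 36.6%. Thinning the longer list took the shared sites of liver to 8.72% and of CD8 T cells to 23.3%, and the shared regions to 23.97% and 48.0%, close to the shares of brain and A549, as lists of equal length require for matched sites; random thinning does not imitate lower read depth. An overlap of 50% of both regions left 15.8, 45.8, 51.8 and 38.8% of regions shared. Of windows, 15.9, 57.1, 45.6 and 39.3% were in both with 2 or more sites, 28.5, 67.9, 63.0 and 51.3% with region middles, and 26.8, 34.7, 35.0 and 34.4% after thinning to the shortest list.

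No paired analysis was possible because each tissue or cell type has 1 merged list. For that reason leaving out replicates was not run either. The better-scored part of each list was not run because the score is constant, and the gene, last-exon, distance and longer-motif alternatives were not run because no annotation or genome of these builds was used. The unknown read depth limits every count here: a site missing from a list cannot be told from a site too weakly covered to be called.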

Other observations

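The chromosome and window counts here, and the tests of one library alone and of the edge grid, were chosen after the results were seen. Windows with many sites were shared more often than windows in general. Of windows with 5 or more sites, 69.1% in liver (62.5 to 75.1%), 67.4% in A549 (64.4 to 70.3%) and 64.2% in CD8 T cells (60.6 to 67.7%) held a position listed in the other library, against 41.1%, 33.2% and 37.9% of all windows with a site. In brain it was 29.2% (26.8 to 31.7%) against 14.9%. More sites give more chances of a match, and whether this rise exceeds what the number of sites gives was not tested. Another 50.2% of these dense brain windows (47.5 to 52.9%) had no liver region at all, compared with 18.2% of dense liver windows without a brain region (13.3 to 23.9%), 15.4% of dense CD8 T cell windows without an A549 region and 19.9% of dense A549 windows without a CD8 T cell region. Over all windows with a site these shares were 61.9% in brain, 20.5% in liver, 26.4% in CD8 T cells and 34.3% in A549. Of all windows with a CD8 T cell site, 21.9% held an A549 region without a precise site.

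Sites were distributed differently over some chromosomes. Mouse chromosome X held 2.60% of brain sites and 1.38% of liver sites, a ratio of 1.88 (block bootstrap interval 1.36 to 2.76). Mouse chromosome 19 held 2.85% of brain and 4.01% of liver sites, a ratio of 0.709 (0.548 to 0.911). These were the highest and lowest mouse ratios, and 4 of 20 chromosomes had an interval without 1. Among human autosomes the highest ratio of CD8 T cells to A549 was 1.53 (1.14 to 2.13), on chromosome 21 with 1.55% and 1.01% of autosomal sites, and the lowest was 0.712 (0.591 to 0.859), on chromosome 15 with 3.16% and 4.44%. Of 22 autosomes 7 had an interval without 1. The intervals are not corrected for the number of chromosomes compared. On these chromosomes, chosen by their site ratios, the ratios of peak region shares were nearer to 1. They were 1.67 on mouse chromosome X, 0.755 on mouse 19, 1.17 on human 21 and 0.827 on human 15. A site ratio thus reflects the sites listed per region as well as the regions.

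Neighbouring sites of a region lay a multiple of 3 nt apart more often than the 33.3% of an even spread. A peculiarity of 1 library is argued against, since the lowest share of the 4 libraries, 36.0% in A549, still lay above 33.3% with its interval. A hypothesis is that codon structure in coding sequence is a candidate source. Pairs 61 to 150 nt apart kept an excess in all 4 libraries, the lowest being 36.2% in CD8 T cells, and pairs 5 to 10 kb apart showed none. Repeats with a 3 nt period could give the same values, so these do not separate codon structure from repeats. Pairs 61 to 150 nt apart are also built from the same sites as the neighbour gaps, so they are not independent of the pattern. Repeated or low-complexity sequence stays open, because in regions with exactly 2 sites the libraries differed: brain stayed at 37.5% (35.8 to 39.2%) and CD8 T cells at 35.6% (33.5 to 37.7%), both above 33.3%, while the intervals of liver, at 36.5%, and A549, at 34.1%, include it.

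Positions listed in both libraries of a species were more often GAC than the others. That regions found in both libraries differ from the rest does not account for all of it, since within such regions the difference was still at least 4.26 percentage points, in liver (2.01 to 6.64). Over all liver sites it was 6.44 points, so in liver a part may come from the regions. In brain, CD8 T cells and A549 the difference was larger within such regions than over all sites. An origin in single-site regions is argued against as well, since averaging over classes of sites per region kept at least 98.3% of the difference. GAC sites may be methylated or captured more strongly and so be called in more lists, but that hypothesis was not tested, as the lists give no signal per site. No biological explanation was tested.

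Sites lay 5' of the middle of their region. Edges set on a 10 nt grid in genome direction are argued against as the whole cause, because the strand-oriented mean stayed at -7.65 nt in the library nearest to 0, A549, although the genome-direction part was 3.89 to 4.24 nt in the 4 libraries. Whether the listing favours candidates near the 5' end cannot be told apart from a true shift: the last site of each region lay 5.55 nt 3' of the middle in brain, 5.47 nt in A549, 3.23 nt in CD8 T cells and 0.613 nt in liver, where the interval includes 0 (-0.159 to 1.33), but being last already moves a site 3'. In regions with a single site the mean was -7.04 nt in brain, -6.51 nt in liver, -7.20 nt in CD8 T cells and -5.82 nt in A549; where that site was not the first candidate the means were 0.640, -0.0804, -0.238 and 0.935 nt, but leaving out first candidates moves the mean 3' by construction. No biological explanation was tested.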
